A study of Mus musculus with 2 samples.

How the data were processed

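The data are ATAC-seq peak lists from the hindbrain of B6NCrl mouse embryos at embryonic day 13.5. Per the labels there were 2 biological replicates, each a pool of male and female embryos, and their libraries were made by Nextera tagmentation. The replicates are separate tissue samples, and their numbers come from the labels. Tests across genes or regions do not measure the spread between embryos.

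The authors deposited 12 peak lists on mm10. Per the file headers, each list was derived from the alignments of a single replicate or of both replicates together, and all but the ranked lists also from a further file whose content is not given in the sources used here. For each replicate there was a list thresholded on the irreproducible discovery rate (IDR), a list called pseudoreplicated, and a list ranked by IDR. For both replicates together there were an IDR-thresholded list (the series list), a conservative IDR-thresholded list, a list called replicated, a pseudoreplicated list and a pair of ranked lists. The aligner, the peak caller, their versions, the read filters and any shift of reads for the transposase are not given in the sources used here. The signal of each summit is the authors' deposited value, never below 1, and what it is relative to is not given in the sources used here. The score of each peak, a whole number up to 1000 that starts at 540 in the thresholded lists, is as deposited by the authors. The −log10 p-value of each peak is also as deposited by the authors. The −log10 q-values and IDR values were not used here, nor were 8 further columns in each of the 4 ranked lists. The read depth of the replicates is unknown, since no read counts were used here, and no correction for depth was made.

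Rows with the same coordinates, which stand for several summits, were collapsed to a single region, and overlapping regions were merged. The summit of a region is that of its row of highest signal. Chromosomes 1 to 19, X and Y were used. Genes were those of the GENCODE vM21 basic annotation on GRCm38.p6, the assembly of mm10, with 21800 protein-coding symbols; 27 symbols that stand for several genes were left out. A region was called a promoter region when its summit lay within 1 kb of any TSS of a protein-coding gene, and otherwise exonic, intronic or intergenic. Regions further than 1 kb from every TSS were called distal and were given to the nearest TSS within 100 kb. The locus of a gene is the sequence nearer to its TSS than to any other, up to that limit.

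The tests, the gene lists, the motifs and the alternatives were fixed before the data were examined, except for a pair of alternatives named in the closing section. There were 25 gene lists with 422 entries, of which Ighm was not found as a protein-coding gene, and 17 families defined by symbol. Some genes stand on several lists: Dll1, Hes1, Hes5 and Notch1 are on the progenitor and the Notch list, Ttr on the choroid plexus and the liver and gut list, Otx2 on the midbrain and the choroid plexus list, and Wnt1 on the hindbrain and the Wnt list. The share of genes with a promoter region was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over lists or over families. The median number of distal regions of a list was set against 10000 random lists of the same size matched on locus length in 10 classes, with a two-sided empirical p adjusted over lists. Hindbrain and forebrain patterning genes were compared on log2(1 + distal regions per 100 kb), and anterior and posterior Hox genes by promoter signal, with two-sided permutation tests of 100000 resamples. The background of overlaps and of genomic classes came from 100 circular shifts within each chromosome. Shares have 95% Wilson intervals.

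For motifs, 33 consensus sequences were searched on both strands in windows of 100 bp to each side of distal summits. The control was a random window for each, on the same chromosome, outside all listed peaks and in the same GC class of 2%; 67 summits without a match were left out. Shares were compared by Fisher's exact test, two-sided, with adjustment over motifs. For a motif absent from either set of windows, a small constant was added to both counts before the log2 ratio. The sequences of the 10 regions of highest signal were aligned to the mitochondrial and the nuclear genome with blastn 2.17.0 at an E-value of 1e-05, and an alignment counted at 90% identity over 50% of the region.

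The genes, regions and motifs named in the text follow a fixed rule. For each list these are the 2 members with the highest promoter signal, the 2 with the most distal regions, and up to 2 members without a promoter region in alphabetical order. Over all genes they are the 10 with the most distal regions and the 10 with the most per 100 kb among loci of at least 50 kb. They also include the 10 regions of highest signal, all Hox genes, and the 5 motifs with the highest and the 5 with the lowest log2 ratio past an adjusted p of 0.05. Further motifs of neural factors, and the genes nearest to the listed regions, were named after their values were seen. Posterior Hox genes, none of which had a promoter region, are given as a group.

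Alternatives were the conservative list, the replicated list, the regions above the median signal, each replicate list alone, promoters within 500 or 2500 bp, TSS limits of 50 or 500 kb, a pseudocount of 0.1, other overlap rules, the pseudoreplicated lists, windows of 50 bp to each side and flanking windows 1 kb from the summit as motif control. The calculations were tested on simulated data. Among simulated lists with no difference 0.16% of 2500 were called in the promoter test, and lists of 24 genes were called in 99.0% of cases at a promoter share of 95% and in 27.0% at 80%. In the distal test 0 of 500 lists with no difference were called, and lists of 24 genes were called in 70.0% of cases at a 3-fold number of regions. The simulated distal counts depended on locus length only and held no further clustering, and the 70.0% rests on few runs. Both rates may therefore differ in the data. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, and samtools 1.23.1.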

Results

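Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into DNA that is not covered by nucleosomes. The tissue was the hindbrain of B6NCrl mouse embryos at embryonic day 13.5, with male and female embryos pooled. The hindbrain gives rise to the cerebellum, the pons and the medulla. There were 2 biological replicates of this single group and no other tissue, stage or treatment. The design therefore allowed no comparison between groups of samples. It allowed the replicates to be compared with each other, and the accessible regions to be described by position, by neighbouring gene and by sequence. All values below rest on n = 2 replicates or on the peak list that the authors made from both replicates together, which is called the series list. Genes, peaks and regions are not replicates, so every test over them describes these libraries only, and every interval covers counting error only. The signal of a peak is the authors' own value and was used to describe, rank or filter peaks within a list, and beyond that only in a rank correlation between the replicates and a comparison of Hox genes. All positions are on mm10, and those given in parentheses for a gene span the annotated gene, not the accessible region.

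The series list held 24503 accessible regions that together covered 26.3 Mb, with a median length of 1067 bp. The list of replicate 1 held 17719 regions and that of replicate 2 held 16750, a mean of 17234.5 ± 685 (SD, n = 2). These covered 18.8 and 17.8 Mb. A longer list, which the authors call replicated, held 62560 regions over 44.7 Mb.

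Promoters of protein-coding genes were the most frequent class of accessible region per base. Of the 24503 regions, 11791 had their summit within 1 kb of a transcription start site (TSS), a share of 48.1% (95% Wilson interval 47.5% to 48.7%). Regions moved at random along their chromosomes lay there in 2.08% ± 0.1197 (SD over 100 shifts), so the observed share was 23.1 times higher. Introns held 20.9% of regions and 36.1% of shifted regions. Intergenic DNA held 28.7% and 59.4%, and exons 2.23% and 2.45%. In the replicate lists the promoter share was 62.0% ± 1.84 (n = 2) and in the longer replicated list it was 23.4%. Of the 12712 distal regions, 9203 lay within 100 kb of a TSS. The median distance of a distal region to its nearest TSS was 42.4 kb.

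The replicates shared most of their accessible regions. Of the regions of replicate 1, 82.6% overlapped a region of replicate 2. Of the regions of replicate 2, 87.4% overlapped replicate 1, and the mean was 85.0%. These are the 2 directions of a single comparison, with 14640 and 14635 shared regions. They differ mainly through list length and give no spread of the agreement. Shifted regions overlapped in 1.38% ± 0.0907 (SD over 100 shifts). The lists had 70.6% of their joint length in common. Across the 14640 shared regions the authors' signal had a Spearman rho of 0.913, which is across regions that are not independent.

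Regions called in a single replicate were mostly distal. Among the 3079 regions of replicate 1 alone, 20.7% were at promoters (95% Wilson interval 19.3% to 22.2%), against 69.1% of its shared regions (68.3% to 69.8%). Among the 2115 regions of replicate 2 alone the share was 22.2% (20.5% to 24.04%), against 69.2%. The median signal of these regions was 5.38 and 5.32, and that of the shared regions 8.13 and 7.85. Of these regions, 93.0% and 93.8% were found in the other replicate's longer pseudoreplicated list. The difference between shared and unshared regions in promoter share was 47.7 percentage points on average over the replicates, and it was 30.2 points when the same number of top regions was taken from each list.

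Of 21800 protein-coding genes, 12383 had an accessible region within 1 kb of a TSS (56.8%); the replicate lists gave 52.2% ± 0.555 (n = 2). Against this background, 25 gene lists for brain regions, cell types and pathways asked which genes have open promoters in this tissue. In the series list, genes of neurons, neural progenitors, axon guidance and the Hedgehog pathway, and housekeeping genes, had open promoters more often than other genes. Genes of immune cells, muscle, liver and gut, surface epithelium and the germ line had them less often. The other genes include large families that are rarely open, such as 1090 olfactory receptor genes with 2 open promoters. A comparison without these families was not made. In all, 15 of the 25 lists passed an adjusted p of 0.05 in Fisher's exact test with Benjamini-Hochberg adjustment over the lists. Of these, 5 were higher and 10 lower than other genes. The split depended on the peak list, with 7 higher and 5 lower in the replicated list, and with only housekeeping genes higher and 16 lists lower among regions above the median signal.

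Markers of postmitotic neurons had an accessible promoter in 22 of 25 genes (88.0%, adjusted p = 0.00522 by Fisher's exact test). Both replicate lists gave 84.0%. The highest promoter signals of this list were at Syt1, the calcium sensor of synaptic vesicle release (14.6; chromosome 10, 108497650 to 109010982), and at the neuronal RNA-binding protein gene Elavl4 (11.05). In the lists of replicates 1 and 2 these genes had signals of 14.4 and 13.8, and of 9.75 and 12.2. In the series list Neurod2 and Nhlh2, which encode transcription factors of differentiating neurons, had no promoter region but 1 and 3 distal regions. Neural progenitor and radial glia genes were open in 20 of 24 (83.3%, adjusted p = 0.0264 by the exact test), and in 72.9% ± 8.84 in the replicate lists (n = 2). Id4, an inhibitor of basic helix-loop-helix factors, led this list with 11.004, followed by the fatty acid binding protein gene Fabp5 with 9.06. The Notch target Hes1 and the RNA-binding protein gene Msi1 had no region at a TSS in the series list, and 3 and 2 distal regions.

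Axon guidance genes had the highest share in the series list, 21 of 22 (95.5%, adjusted p = 0.000667 by Fisher's exact test), with 75.0% ± 3.21 in the replicate lists (n = 2). The ephrin receptor gene Ephb1 (9.26) and the plexin gene Plxna2 (8.74) had the strongest promoters, and only Slit1, a repulsive guidance ligand, had none. Hedgehog pathway genes were open in 11 of 12 (91.7%, adjusted p = 0.0325 by the exact test), and in 75.0% in both replicate lists, led by the co-receptor Cdon (9.35) and the signal transducer Smo (8.90). Gli1, a transcriptional target of the pathway, was the member without a promoter region. Housekeeping genes were open in 15 of 16 (93.8%, adjusted p = 0.00522 by the exact test), led by the elongation factor gene Eef1a1 with 13.3 and the succinate dehydrogenase gene Sdha with 12.3. The ubiquitin gene Ubc was the exception. Notch pathway genes (11 of 16, adjusted p = 0.564) and Wnt pathway genes (14 of 23, adjusted p = 0.948) did not pass the exact test in the series list. The Notch list did pass in the conservative list (30.7 points above other genes, exact test, adjusted p = 0.0354) and in the replicated list (36.1 points, adjusted p = 0.00281; range over all alternatives 0.00281 to 0.907). Hey2, a Notch effector, had the highest promoter signal of any list member, 15.2. Maml1, a Notch co-activator, had 11.1, and the Wnt receptor genes Fzd1 and Lrp6 had 8.80 and 7.76.

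Lymphocyte genes had an accessible promoter in none of 12 genes, Cd19 and Cd3d among them (adjusted p = 0.000526 by Fisher's exact test), and the replicate lists gave none either. A single gene was open among the 15 liver and gut genes (adjusted p = 0.000585), the 12 microglia and macrophage genes, the 12 surface epithelium genes and the 12 germ line and pluripotency genes (adjusted p = 0.00252 for each of the last 3, exact test). These genes were Ttr (4.05), Irf8 (5.14), Krt10 (4.89) and Dazl (10.0). Ttr, which encodes transthyretin, is also a choroid plexus gene and stands on both lists. Dazl, a germ cell RNA-binding protein gene, was open in both replicate lists, with 9.69 and 9.45, whereas Ttr, Irf8 and Krt10 were open in neither. Muscle genes were open in 2 of 13 (15.4%, adjusted p = 0.00855) and endothelial genes in 3 of 13 (23.1%, adjusted p = 0.0365, exact test). The muscle promoters were those of Actc1 (3.80), which neither replicate list held, and Myh7 (2.35), and the strongest endothelial promoter was that of the VEGF receptor gene Kdr (5.64), which neither replicate list held. In the lists of replicates 1 and 2, muscle genes were open in 0 and 1 of 13 and endothelial genes in 1 and 0 of 13.

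Neurotransmitter identity genes, a list of transmitter enzymes, transporters and regulators, were open in 6 of 20 (30.0%, adjusted p = 0.0365 by Fisher's exact test). Tph2, the enzyme of neuronal serotonin synthesis, had a signal of 5.46 but no region in either replicate list, the choline transporter gene Slc5a7 had 5.39, and the choline acetyltransferase gene Chat and the dopamine hydroxylase gene Dbh had no promoter region. Forebrain patterning genes were open in 8 of 25 (32.0%, adjusted p = 0.0307 by the exact test), and in 22.0% ± 8.49 in the replicate lists (n = 2). They were led in the series list by the homeobox genes Arx (6.998) and Lhx2 (5.32), and Dlx2 and Dlx5 had no promoter region there. Hindbrain and cerebellar patterning genes were open in 20 of 35 (57.1%, 95% Wilson interval 40.9% to 72.0%), which did not pass in the series list (exact test, adjusted p = 1.0). This list passed in opposite directions elsewhere, with 21.9 points more than other genes in the replicated list (exact test, adjusted p = 0.0152) and −20.4 points with replicate 2 alone (adjusted p = 0.0279; range over all alternatives 0.000360 to 1.0). Mab21l2 (7.42) and Mafb, a hindbrain segmentation gene (7.15), led them, and Barhl1 and En1 had no promoter region. The replicate lists gave 35.7% ± 6.06 for this list (n = 2).

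The remaining lists did not pass Fisher's exact test in the series list. By this exact test they were midbrain patterning genes (6 of 11, adjusted p = 1.0), astrocyte genes (7 of 10, adjusted p = 0.631), choroid plexus and roof plate genes (7 of 12, adjusted p = 1.0), mesenchyme genes (7 of 15, adjusted p = 0.564), erythroid genes (5 of 14, adjusted p = 0.243) and oligodendrocyte lineage genes (4 of 13, adjusted p = 0.132). The oligodendrocyte, erythroid and mesenchyme lists did pass as lower than other genes with either replicate alone and among regions above the median signal, and astrocyte genes in the latter only; the oligodendrocyte list also passed in the conservative list and the erythroid list with promoters within 500 bp. Single members of these lists had strong promoters. The homeobox gene Pitx2 had 10.1 and Snai2, a zinc finger gene of neural crest and mesenchyme, had 11.1. Enpp2, which encodes autotaxin, had 8.15, the glial factor gene Olig1 7.62 and the erythroid spectrin gene Sptb 5.79. The call held in every alternative for 6 lists, namely posterior Hox, microglia, liver and gut, germ line, lymphocyte and housekeeping genes; with replicate 2 alone it ended for progenitor and axon guidance genes, and with either replicate alone for Hedgehog genes. It ended in the replicated list for muscle, epithelium and endothelial genes, in the conservative list for forebrain and neurotransmitter genes, with promoters within 2500 bp for forebrain, neurotransmitter and endothelial genes, and above the median signal for neuron genes, whose difference fell from 31.2 to 4.59 points. Among regions above the median signal the difference from other genes turned to −16.2 percentage points for axon guidance, −18.4 for Hedgehog, −10.1 for progenitor and −32.0 for hindbrain patterning genes, and in the replicated list it turned to 12.1 for forebrain patterning and 1.12 for neurotransmitter genes.

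Open and closed promoters were found at further members of these lists. In the series list promoters were open at the sensory factor gene Pou4f1 (signal 7.87), at Foxj1, a factor of ciliated cells (7.03), at the growth factor receptor gene Pdgfra (6.23), at the endothelial factor gene Erg (5.52) and at the glial genes Aldoc (5.52) and Gja1 (5.49); the last 3 were in the list of replicate 1 and not of replicate 2. The glycophorin gene Gypa, which the list of replicate 1 did not hold, had 5.34, Foxc1, a factor of meninges, 5.04, and the blood factor gene Tal1 3.83, which neither replicate list held. The series list held no promoter region at the midbrain genes Dmbx1, Foxa1 and Foxa2, the oligodendrocyte genes Cspg4, Mag and Sox8, the astrocyte genes Aqp4 and Gfap, or the roof plate and choroid plexus genes Bmp4 and Clic6. The same held for Cdh5, Eng and Robo4 of endothelium, Alas2 and Ermap of erythroid cells, Col3a1, Dcn and Pdgfrb of mesenchyme, and Ckm and Des of muscle. It also held for Aif1, C1qa, Ptprc and Spi1 of microglia, Afp, Alb and Apoa1 of liver and gut, Cdh1, Cldn4, Epcam and Grhl2 of epithelium, and Ddx4, Dppa3, Nanog and Sycp3 of the germ line. Among pathway genes it held for the Notch ligand gene Dll3 and the Wnt genes Dkk1 and Fzd10. Many of the genes named as closed had a promoter region in the longer replicated list. These were Dkk1 (5.08, and 3.94 in replicate 2), Dll3, Dlx2, Dlx5, Epcam, Nhlh2, Sox8, Msi1, Foxa1, Foxa2, Hes1, Des, Ubc, Chat, Sycp3, Neurod2, En1, Olig3, Slit1, Fzd10, Cdh1, Grhl2 and Gli1 (2.10).

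**Figure D1:**
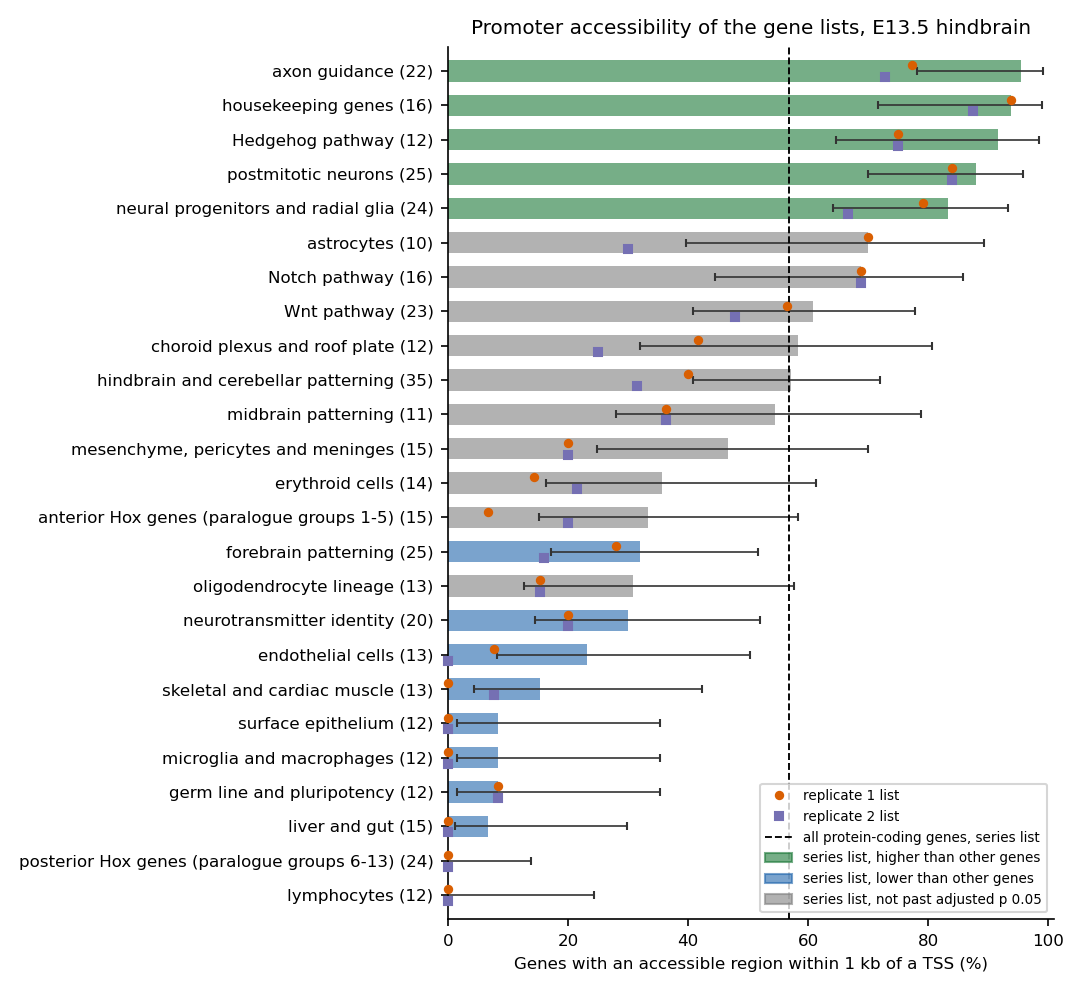
Share of genes of each list with an accessible region within 1 kb of a TSS (x axis, percent), with the number of genes in parentheses. Bars give the series list with 95% Wilson intervals, points the list of each replicate, and the dashed line the 56.8% of all protein-coding genes; shares run from 0 of 24 posterior Hox genes to 21 of 22 axon guidance genes.

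The Hox genes, which set position along the body axis, differed by paralogue group. Promoters were accessible at 5 of the 15 anterior genes of paralogue groups 1 to 5, whose expression reaches into the hindbrain, and at none of the 24 posterior genes of groups 6 to 13 (Fisher's exact test, two-sided p = 0.00522). The open promoters were those of Hoxd1, Hoxa1, Hoxb4, Hoxa2 and Hoxa4, with signals of 6.70, 6.19, 4.69, 4.26 and 4.22. The annotated gene spans 74762980 to 74765142 on chromosome 2 for Hoxd1 and 96318267 to 96321638 on chromosome 11 for Hoxb4. On chromosome 6 it spans 52155590 to 52158317 for Hoxa1, 52162417 to 52164831 for Hoxa2 and 52189671 to 52191753 for Hoxa4. The regions at Hoxa2 and Hoxa4 lay just outside these spans, at 52164988 to 52165394 and at 52191858 to 52192490. The anterior genes without a promoter region were Hoxa3, Hoxa5, Hoxb1, Hoxb2, Hoxb3, Hoxb5, Hoxc4, Hoxc5, Hoxd3 and Hoxd4. Hoxa3 was scored only at its annotated TSS at 52213115, between those of Hoxa6 and Hoxa7. Far from that TSS but inside its annotated span, the series list held regions at 52172135 to 52173081 (signal 5.58) and at 52175823 to 52176367 (3.52). Mean promoter signal, with 0 for a gene without a region, was 1.74 for anterior and 0 for posterior genes (permutation test, two-sided p = 0.00526). Since every posterior gene was at 0, this test restates the count of open promoters and adds nothing on signal strength. Neighbouring Hox genes can share a region, so these counts are not independent. Among the gene lists, posterior Hox genes were lower than other genes (adjusted p = 4.4e-08 by Fisher's exact test), and anterior Hox genes did not pass in the series list (33.3%, adjusted p = 0.115) but were lower with either replicate alone and above the median signal. The replicate lists held fewer of these promoters. Replicate 1 had only Hoxa1, and replicate 2 had Hoxa1, Hoxa2 and Hoxd1. With replicate 1 alone the comparison gave an exact p of 0.385, and the range over all alternatives was 0.00306 to 0.385. In the replicated list 12 anterior and 7 posterior genes had a region. The Hoxc cluster held no region of the series list and 7 of the replicated list.

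**Figure D2:**
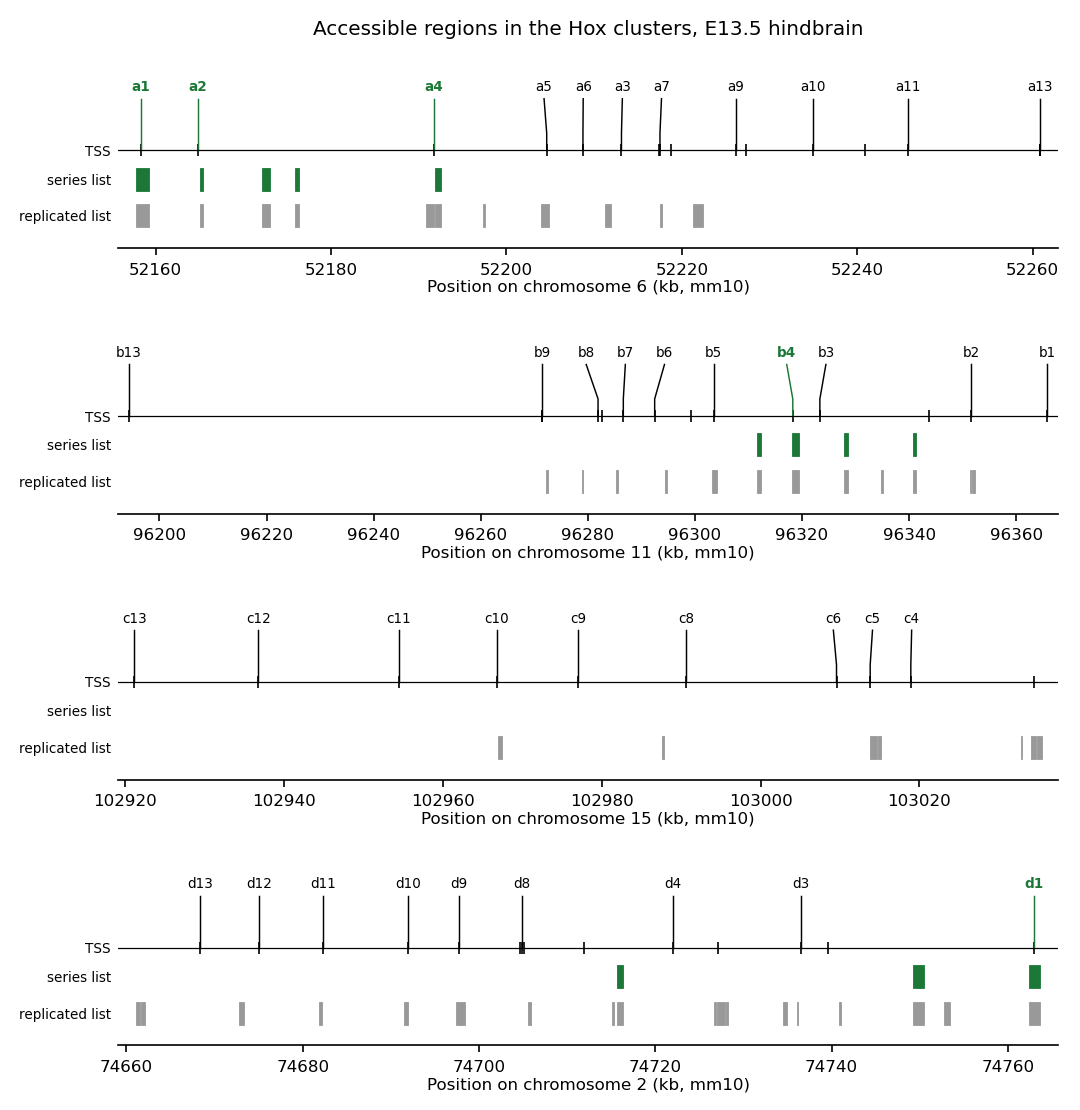
The Hox clusters on mm10 (x axis, kb), with a tick at each annotated TSS, a label at 1 TSS of each gene, and blocks for the regions of the series list (green) and of the longer replicated list (grey). Genes in green have a region of the series list within 1 kb of a TSS; these are 5 anterior genes and no posterior gene.

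In the series list, distal accessible regions were more frequent around progenitor, astrocyte, Notch, Hedgehog and axon guidance genes than around random genes with loci of similar length. Each distal region was given to the gene with the nearest TSS within 100 kb. The median number of distal regions was 2 for progenitor genes (adjusted p = 0.0050, permutation test with 10000 random lists), 2.5 for astrocyte genes (adjusted p = 0.0050), 1.5 for Notch genes (adjusted p = 0.00833), 2 for Hedgehog genes (adjusted p = 0.0270) and 2 for axon guidance genes (adjusted p = 0.0225). For each of these lists, 95% of random lists had a median between 0 and 1. Nfia, a nuclear factor I gene, had 7 distal regions, and 5 and 4 in the replicate lists. Pax6, a regulator of neural progenitors, had 5, as did Ptprz1, Jag1, Notch1, Gli2 and Plxna1. The lists of replicates 1 and 2 held 3 and 2 for Pax6, 5 and 2 for Ptprz1, and 2 and 1 for Jag1. They held 1 and 1 for Notch1, 3 and 3 for Gli2, and 1 and 2 for Plxna1. In the series list the Hedgehog receptor gene Ptch1 had 6 and the semaphorin gene Sema6a had 7. The replicate lists held 4 and 3 for Ptch1, and 2 and 4 for Sema6a.

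The other 20 lists did not pass on the median. With the list mean, chosen after seeing the data, hindbrain patterning, neurotransmitter and anterior Hox genes passed in the series list, and hindbrain patterning genes also passed on the median with promoters within 500 bp. With the settings used throughout, the medians of these 20 lists were 1 for hindbrain patterning (adjusted permutation p = 0.868), forebrain patterning (0.761), midbrain patterning (1.0), neuron (0.868), neurotransmitter (0.276), oligodendrocyte (0.276), choroid plexus (0.860) and Wnt genes (0.865). They were 0 for anterior and posterior Hox, endothelial, microglia, erythroid, mesenchyme, muscle, liver and gut, epithelium, germ line, lymphocyte and housekeeping genes, each with an adjusted p of 1.0. For each of these the middle value of the random medians was also 0. This p was therefore fixed in advance, and the test could not have called such a list lower. Within these 20 lists the homeobox gene Meis1 had 6 distal regions. Olig3, a gene of dorsal hindbrain progenitors, had 5 and no promoter region, Nr2f1 had 8, Myt1l 7 and Wnt7b 6. Gap43, Gad2 and Pax3 had 4 each, Bcl11b and the endothelial cadherin gene Cdh5 3, and Pou4f1, Foxa2, Sox8, Foxj1, Robo4, Pdgfrb, Epcam, Hoxb3, Hoxc4 and Hoxd3 2. The count of lists passing was 0 among regions above the median signal, 2 with a limit of 50 kb and 9 in the replicated list, and no call held in every alternative. With replicate 1 alone only progenitor, astrocyte and Notch genes passed, with replicate 2 alone progenitor, hindbrain patterning and neurotransmitter genes, and Hedgehog genes also lost the call in the conservative list. In the replicated list the hindbrain patterning genes had a median of 6 distal regions, against 1 to 3 in 95% of random lists (adjusted permutation p = 0.0025); over all alternatives the adjusted p of this list ranged from 0.0025 to 1.0.

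Hindbrain patterning genes had a median of 1.39 distal regions per 100 kb of locus (35 genes) and forebrain patterning genes 0.765 (25 genes). The mean difference was 0.32 on the log2 scale with a pseudocount of 1, and it did not pass the permutation test (two-sided p = 0.130). In the replicated list the difference was 0.54 (permutation p = 0.0199), with 5.24 and 3.14 regions per 100 kb, and among regions above the median signal it was 0.29 (permutation p = 0.0459). The permutation p ranged from 0.0199 to 0.336 over all alternatives, and hindbrain genes had the higher mean in each.

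Over all protein-coding genes, the most distal regions in a locus were found at Maml3, Nrxn3, Sertad2, Ank3 and Zfp516. Maml3, a Notch co-activator gene, had 12 (chromosome 3, 51685907 to 52105076), and 12 and 6 in the replicate lists. Nrxn3, a synaptic adhesion gene, had 11. Sertad2, the ankyrin gene Ank3 and Zfp516 had 10 each, and Pde4d, Frmd4a, Auts2, the co-repressor gene Ncor2 and Acot11 had 9 each. Per 100 kb of locus the densest were Acot11 (10.3; chromosome 4, 106744555 to 106804998), Tex14 (10.0), Trim27 (9.92), Eapp (8.90), Rhbg (8.53), Ddit4 (8.39), Notch1 (7.58), Parp16 (7.42), Shf (7.31) and A830005F24Rik (7.27). Some of these clusters lay at small RNA genes, which the protein-coding annotation does not count as promoters. The replicate lists held few regions at Notch1 (1 and 1), Ddit4 (1 and 2) and A830005F24Rik (1 and 1). They held 8 and 8 at Tex14, 6 and 6 at Eapp, and 3 to 7 at the other loci of this ranking.

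Gene families grouped by symbol differed widely in their share of open promoters. Ribosomal protein genes had an accessible promoter in 76 of 79 (96.2%, adjusted p = 4.7e-15 by Fisher's exact test), replication-dependent histone genes in 62 of 68 (91.2%, adjusted p = 1.4e-09) and zinc finger genes named Zfp in 306 of 365 (83.8%, adjusted p = 9.1e-28). Olfactory receptor genes had one in 2 of 1090 (0.183%, 95% Wilson interval 0.0503% to 0.667%). Vomeronasal receptors had one in 1 of 325 (adjusted p = 5.0e-117), keratins in 1 of 49 (adjusted p = 3.6e-16, exact test) and beta-defensins in none of 42 (adjusted p = 1.6e-15). Clustered protocadherins, cell surface proteins of neurons, had one in only 4 of 55 (7.27%, adjusted p = 2.2e-14 by the exact test), and both replicate lists gave the same share. The Hox family as a whole was lower with 5 of 39 (exact test, adjusted p = 4.3e-08). In all 9 of 17 families passed, and 8 of these passed in every alternative, the exception being the Hox family. Families of other neural transcription factors did not pass the exact test in the series list, with 4 of 4 Ebf genes (adjusted p = 0.236), 4 of 5 Zic and 5 of 12 LIM homeobox genes (adjusted p = 0.564 each), 3 of 4 nuclear factor I genes (0.835), 4 of 6 Irx (0.855), 8 of 15 POU (0.906), 11 of 19 Sox and 5 of 9 Pax genes (1.0 each). Pax genes did pass as lower among regions above the median signal (a difference of −43.4 points).

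The motifs of CTCF, RFX factors and POU factors were among the most enriched in distal regions. Windows of 201 bp around 12645 distal summits were compared with as many random windows of the same chromosome and GC content (54.0% and 53.9%). Of 33 fixed motifs, 18 were more frequent and 2 less frequent in distal windows at an adjusted p of 0.05 (Fisher's exact test, Benjamini-Hochberg over motifs). The motif of the insulator protein CTCF stood in 6.02% of distal and 0.142% of control windows, a log2 ratio of 5.40 (exact test, adjusted p = 4.0e-202; 5.36 ± 0.91 in the replicates, n = 2). The motif of RFX factors, regulators of cilium genes, followed with 4.94 (exact test, adjusted p = 5.9e-62; 5.20 ± 0.36). CTCF and RFX had 18 and 8 control windows with the motif in the series list, so their SDs also hold counting error of the controls. The nuclear factor I palindrome had 4.09 (exact test, adjusted p = 0.000280) but rested on 17 distal windows and 1 control window. The POU octamer had 2.09 (exact test, adjusted p = 1.7e-38) and the ETS motif 1.98 (adjusted p = 2.0e-10).

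Among motifs of neural factors, the homeodomain site TAATTA had a log2 ratio of 1.85 and the Pbx-Hox composite site 1.74, and against windows flanking the same summits these fell to 0.20 and 0.56. The flanking windows were not matched on GC, with a content of 44.5% against 54.1% at the summits. Motifs of broadly expressed factors were also more frequent, with 1.31 for Sp/KLF and 0.94 for the E-box CACGTG of Myc and Usf. NRF1 had 1.49 from 28 distal and 10 control windows, and 4.04 ± 2.14 in the replicates (n = 2). The replicates gave 5.55 and 2.52, and the first of these rests on almost no control windows with the motif. This SD therefore does not measure the spread between replicates. The E-box CAGCTG, bound by Ascl1 and Ptf1a, was in 23.5% of distal and 13.2% of control windows (0.83), and the Sox site had 0.77 and the nuclear factor I site TTGGCA 0.69. The lowest ratios past the test were those of the E-box CAGGTG (−0.75, with −0.86 ± 0.07 in the replicates, n = 2) and of the Otx/Pitx site (−0.28), which were less frequent in distal windows, and of NFY (0.23), AP-1 (0.32) and the E-box CAGATG (0.39), which were more frequent. In the replicate lists NFY had a higher ratio, 0.61 ± 0.03, and the E-box CAGATG had 0.30 ± 0.04 (n = 2). CAGGTG, bound by Zeb and Snai repressors, was in 12.5% of distal and 21.1% of control windows, and its ratio was −0.09 against windows flanking the same summits. The call and direction held in every alternative for 14 of the 20 motifs. The exceptions were the nuclear factor I palindrome, whose call ended in both replicate lists, and the ETS, Mef2, AP-1, NFY and Otx/Pitx sites; NFY turned to −0.18 in the replicated list and ETS had 0.33 there.

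**Figure D3:**
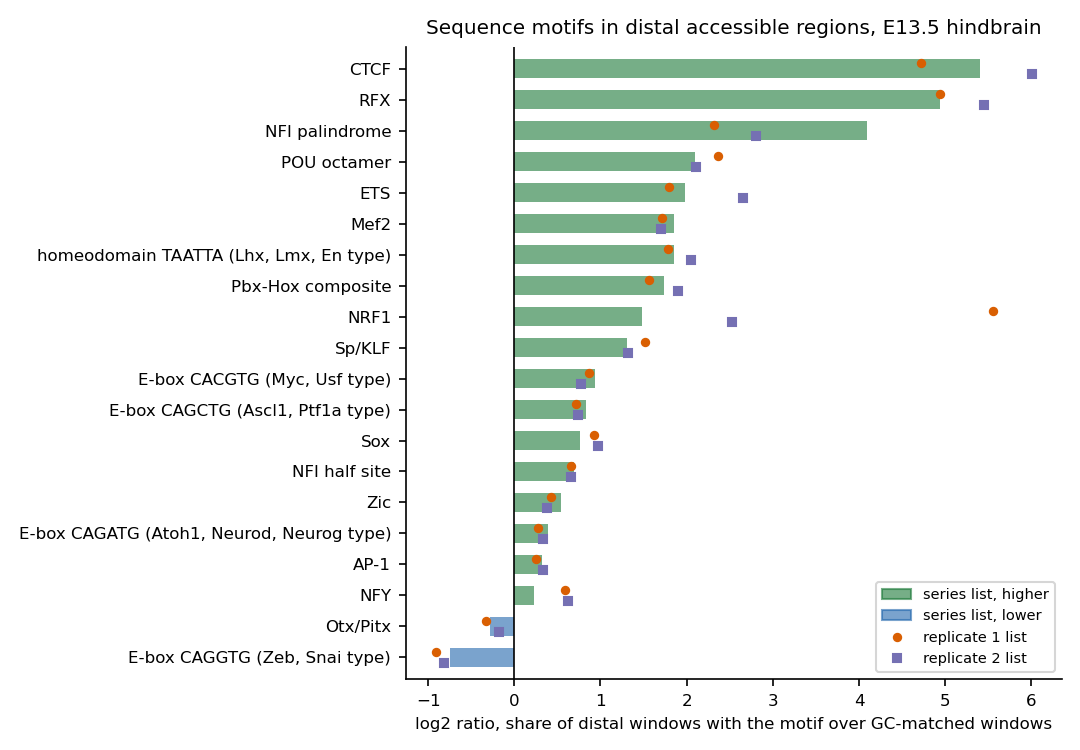
Log2 ratio of the share of distal windows with a motif over GC-matched control windows (x axis) for the 20 motifs past an adjusted p of 0.05. Bars give the series list and points the replicate lists; CTCF is highest with 5.40 and the E-box CAGGTG lowest with −0.75.

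Accessible regions were unevenly spread over chromosomes. Chromosome 11 had the highest density, 9.25 ± 0.295 regions per Mb in the replicates (SD, n = 2), and chromosome 17 had 8.23 ± 0.216. Chromosome 14 had the lowest density of the autosomes, 5.17 ± 0.209. Chromosome X had 3.20 ± 0.0744 regions per Mb, which was 48.1% ± 0.792 of the autosomal median of 6.65, whereas its density of coding genes was 71.2% of the autosomal median. This gap was larger than the spread between replicates. Male and female embryos were pooled, and no correction for the copy number of chromosome X was made. The cause of the gap was not tested. Chromosome Y had 14 regions in the series list.

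**Figure D4:**
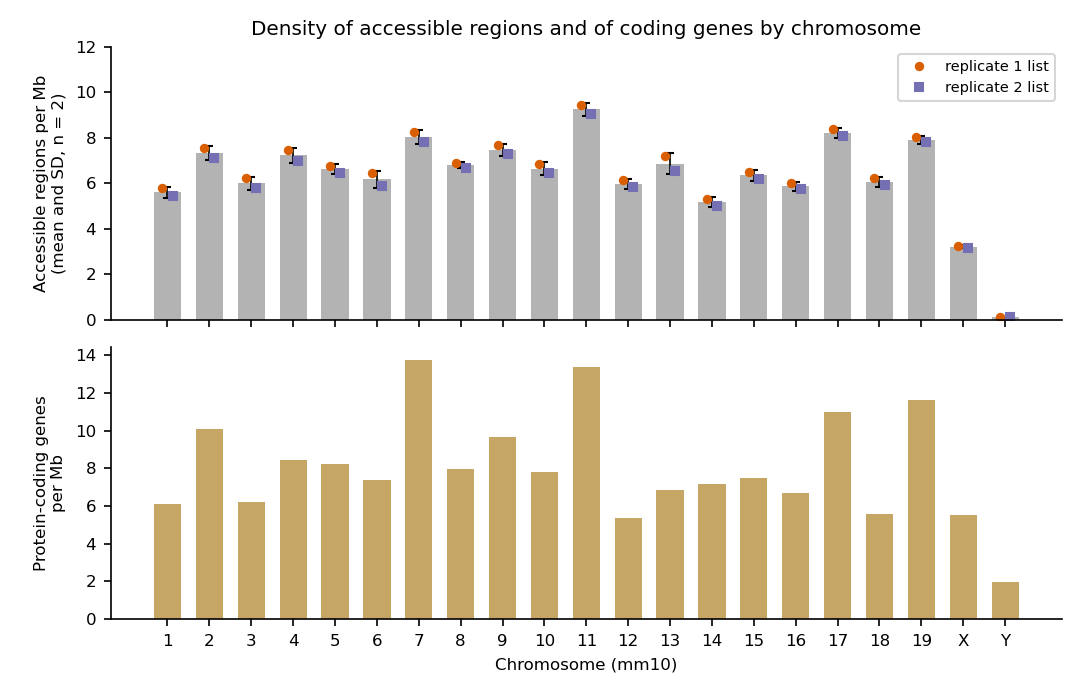
Accessible regions per Mb (upper panel, bars mean and SD over 2 replicates, points the replicate lists) and protein-coding genes per Mb (lower panel) by chromosome. Chromosome X has 3.20 regions per Mb and chromosome 11 has 9.25.

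The 10 regions of highest signal were short and distal. The highest lay on chromosome X at 143482934 to 143483180 (signal 54.8, intergenic, 35532 bp from the TSS of Pak3), and the next on chromosome 2 at 69355469 to 69355735 (50.7, 12987 bp from Abcb11) and at 3964426 to 3964690 (42.4, 53182 bp from Frmd4a). Further regions lay on chromosome 5 at 60042765 to 60043133 (33.7), on chromosome 10 at 96077546 to 96077955 (33.5), on chromosome 12 at 97061367 to 97061856 (29.0) and on chromosome 4 at 80002696 to 80003056 (25.5). The last were on chromosome 8 at 19784410 to 19785226 (25.4), in an intron of Cldn34d on chromosome X at 76598493 to 76599194 (24.4) and on chromosome 6 at 9889882 to 9890225 (23.3). All 10 were found in both replicate lists, with signals of 21.4 to 52.8. At 6 of them the summit lay in sequence similar to the mitochondrial genome, and at 3 others in sequence with another nuclear alignment. For the regions on chromosome X these alignments were short, 106 bp of 247 bp and 104 bp of 702 bp.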

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

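The checks in this part were chosen after the data were seen. The ranked list of the series held 75 regions whose score passed the threshold of 540 but which the thresholded list does not contain, and none of the comparisons above used them. Their joint length was 57.8 kb. The one with the highest −log10 p-value of the whole ranked list, 9734, lay on chromosome 1 at 24611587 to 24616165. It was 4579 bp long and matched the mitochondrial genome from position 6413 to 10990 at 99.96% identity. It was the only 1 of the 75 with a mitochondrial alignment. Others lay on chromosome 6 at 103648978 to 103649357 with a signal of 42.0 and on chromosome 2 at 98666171 to 98667343 with a signal of 8.66.

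A further 48 regions past the same score lay on sequences of the assembly that are not placed on a chromosome, and the thresholded list held none of these sequences.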

How the results depend on the processing

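The list mean in place of the median and the windows without repeat-masked bases were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because there was a single group of samples. Over the alternatives, 124 of 175 differences for the promoter lists kept their direction and their side of the threshold, 13 lost the call, 17 gained it and 21 changed sign. For the distal lists these numbers were 222, 18, 10 and 0 of 250, for the families 106, 1, 1 and 11 of 119, and for the motifs 198, 13, 20 and 33 of 264. Sign changes of 5 motifs (14 values) and 7 families (10 values) that passed in no setting are counted here and not listed. The number of promoter lists, families and motifs past the threshold stayed within 1.5 times the reported number in each alternative, but the promoter lists split into 1 to 7 higher and 5 to 16 lower than other genes. For values below the cause was not tested, and the check of the promoter share could not decide it. Unknown depth limits the replicate lists, and at a planted promoter share of 80% the simulated lists of 24 genes were called in 27.0% of cases.

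With the replicated list the promoter share was 23.4%, and 9 lists passed the distal test. Differences in promoter share turned positive for anterior Hox (16.1 points), forebrain (12.1), midbrain (17.9), neurotransmitter (1.12), mesenchyme (2.79) and Pax family genes (2.79). The hindbrain to forebrain difference was 0.54, and the log2 ratios of Ebf and NFY turned to 0.48 and −0.18. Among regions above the median signal the promoter share was 70.0%, 0 lists passed the distal test, the Hox difference was 6.67 points, and the hindbrain to forebrain difference was 0.29. Promoter differences there turned to −32.0 points for hindbrain patterning, −10.1 for progenitors, −43.4 for astrocytes, −18.4 for choroid plexus, −5.92 for Notch, −18.4 for Hedgehog, −8.64 for Wnt and −16.2 for axon guidance, and log2 ratios to −0.19 for Meis/Tgif, −0.29 for TEAD, 0.11 for Runx and −0.14 for posterior Hox/Cdx.

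With promoters within 500 bp the promoter share was 45.3%, and the differences were −6.12 points for choroid plexus and −3.94 for Wnt genes. With 2500 bp the share was 50.7% and 3 lists passed the distal test. With a TSS limit of 50 kb 2 lists passed, and with the list mean 8. In the pseudoreplicated lists the replicates held 46076.5 regions on average, shared 75.6%, had a rho of 0.853, differed by 31.5 points in promoter share between shared and unshared regions, and had 32.5% of the autosomal density on chromosome X. Overlap of 50% of each region gave a rho of 0.919 and 46.6 points, summits within 100 bp gave 74.2% shared, and the same number of top regions gave 0.844 and 30.2 points. Each summit counted on its own gave 51156.5 per replicate.

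For the motifs, the conservative list turned Ebf to 0.017 and Runx to 0.0034. Flanking control windows turned Ebf to 0.89, TEAD to −0.080 and posterior Hox/Cdx to −1.06. Windows of 50 bp to each side turned Ebf to 0.035 and HNF4 to 0.29, and windows without repeat-masked bases turned Otx/Pitx to 0.22. Leaving out a replicate gave ranges of 60.7% to 63.3% for the promoter share, 6.67 to 20 points for the Hox difference and 3 to 3 lists in the distal test. The ranges were −20.4 to −12.6 points for hindbrain patterning, −21.8 to 17.5 for astrocytes, −26.8 to −10.9 for choroid plexus and −3.94 to 3.98 for Wnt genes. They were −0.44 to −0.014 for Meis/Tgif, −0.096 to 0.16 for Runx and −0.12 to −0.015 for posterior Hox/Cdx.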

Other observations

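The counts at non-coding genes and the tests on the regions without a mitochondrial alignment were chosen only after the result was seen. Part of the regions called distal lay at promoters of genes that code for no protein. Of the 12712 distal regions, 724 (5.70%, 95% Wilson interval 5.31% to 6.11%) had their summit within 1 kb of the TSS of a long non-coding RNA gene, against 0.787% ± 0.0796 of shifted regions (SD over 100 shifts). Genes of tRNA, which RNA polymerase III transcribes, were near 107 distal regions (0.842%), against 0.0241% ± 0.0159 of shifted regions, and 142 of 403 tRNA genes had such a region. Genes of small nuclear or nucleolar RNA were near 62 (0.488% against 0.213% ± 0.0462) and microRNA genes near 56 (0.441% against 0.144% ± 0.0364).

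These genes account for some of the densest loci. All 8 distal regions given to Tex14 lay within 1 kb of snRNA or snoRNA genes, among them Rnu3b1 to Rnu3b4 and Rnu1a1, and all 6 of Eapp did too. All 7 of Trim27 lay at tRNA genes. None of the regions of Acot11 (9), Ddit4 (5) or Notch1 (5) lay at a gene of these classes. Among regions at named microRNA genes Mir1983 had the highest signal, 15.9, and members of the Mir344 cluster on chromosome 7 had signals of 11.5 (Mir344c), 10.2 (Mir344), 9.87 (Mir344i), 9.36 (Mir344f) and 9.23 (Mir344-2). Mir210 had 10.2 and Mirlet7i 9.13.

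The 10 regions of highest signal may hold reads that belong elsewhere, and for reads from mitochondrial DNA 5 of the 10 aligned to the mitochondrial genome over at least 50% of their length, between the bounds set beforehand, while 11 of all 24503 regions did (0.0449%). Under the E-value and identity limits used here, no mitochondrial alignment of any length was found for 4 of the regions. These 4 were picked for that lack. Their number could therefore not have favoured reads from mitochondrial DNA, and no conclusion on that explanation is drawn from it. For reads shared with other nuclear copies, 5 of the 10 had another nuclear alignment, against 6 of 200 random other regions (3%). Of the 4 regions without a mitochondrial alignment, 1 was among the 5. Counting alignments of any length, 3 of these 4 had another nuclear alignment over the summit, so this stays open for them. How often other regions have such an alignment was not counted. The region on chromosome 2 at 3964426 to 3964690 had neither, and no biological explanation was tested.

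The promoter share fell with peak strength, from 89.2% in the strongest 6256 regions of the replicated list to 5.53% in the weakest 6256, and it differed between lists. List length and strength of the regions kept could account for this. Shortened to its 24503 strongest regions, the replicated list had a promoter share of 48.3%, against 48.1% in the series list. Of the regions of the series list, 99.7% overlapped the replicated list. Such a match was therefore likely in advance and does not decide the cause. The lower depth of one replicate than of the pool is a candidate explanation for the 62.0% of the replicate lists. The series list shortened to 17234 regions had 61.9%, but 98.1% and 98.7% of the replicate regions overlapped the series list. This match therefore could not tell depth from list length or strength. Depth itself was not measured here, and no biological explanation was tested.

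The E-box CAGGTG was less frequent in distal windows than in GC-matched windows, whereas CAGCTG and CAGATG were more frequent. Repeats that hold CAGGTG and are rare in accessible regions were tested by leaving out every window with a repeat-masked base, with bounds set before the result was seen. The log2 ratio was then −0.72 (13.6% against 22.3% of windows), within the range that excludes repeats as the whole cause. Against flanking windows, which have a GC content of 44.5%, the ratio was −0.09, so the choice of control windows stays open as a source. No biological explanation was tested.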
